A study of Mus musculus with 8 samples.

How the data were processed

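RNA from 8 female C57BL/6 mouse tongue samples was sequenced: 5 normal tongues that had received no 4-nitroquinoline 1-oxide (4-NQO) and 3 tongue squamous cell carcinomas induced with it. 4-NQO is a water-soluble quinoline carcinogen that forms DNA adducts and is widely used to induce oral cancer in rodents. Groups were taken from the sample titles. Per the labels' protocols, RNA was column-purified with DNase treatment and checked on a Bioanalyzer. Libraries came from the Illumina TruSeq RNA workflow, which selects polyadenylated RNA on poly-T beads before fragmentation and random priming. The labels do not say whether each sample is a separate animal, so the p-values may measure only the spread between these samples, which could be partly technical.

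The file analysed was the authors' deposited table of their own comparison, with 23235 rows, a locus and RefSeq identifiers per row. Its expression values are FPKM (fragments scaled to transcript length and to all mapped fragments), and the deposited table holds a single FPKM per gene for each group, with no value per sample. Total counts and the depth of each sample are therefore unknown, and no SD, n or interval from counts can be given. Per the file headers, each row also carries the log2 fold change of 4-NQO over control, a test statistic, a p-value, a q-value and the authors' call. The sign of the deposited statistic is opposite to that of the fold change in 100% of the tested rows with a finite fold. Per the submitters' processing notes, the authors named GSNAP 2011.11.17, edgeR and the build GRCh37, with no role given. GRCh37 is a human assembly. The program that produced the table and the mouse build of its loci are not given in the sources used here. The loci are not those of GRCm38: of 20522 genes compared with RefSeq names of GRCm38.p6, 1.02% had the same start. The table reaches position 197002909 on chromosome 1, past the last GRCm38 gene end there at 195291439. Coordinates printed here are the table's own, shifted to count from 1, and were not converted.

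A row was counted as tested where its status was OK, which held for 15783 rows. Status was NOTEST in 7242 rows, LOWDATA in 154, HIDATA in 30 and FAIL in 26. HIDATA rows list an exact 0 for very abundant transcripts or for genes that share a locus with others. Those zeros are failed estimates, and such genes are reported only as listed at 0. In 97 tested rows a group was at 0, and no fold is given for them. Spreadsheet software had turned 25 symbols into dates. All 25 were recovered through their RefSeq accessions, and 89 rows that join several symbols were kept as they are. RefSeq accessions matched the reference gene names in 22816 rows.

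Because the file holds only the authors' comparison, no new test between groups was made. A gene was called where the deposited q-value was under 0.05, which matched the authors' own call in every row of the file. The deposited fold change equals the log2 ratio of the deposited FPKM values. A standard error of each log2 fold change was derived as the fold change divided by the deposited statistic, since a two-sided normal p from that statistic equals the deposited p-value. These standard errors are written as ± values. A second count was restricted to genes changed at least 4-fold, a log2 fold change of at least 2. The deposited q-values are not a Benjamini-Hochberg adjustment over the tested rows: they imply between 10746 and 38173 tests.

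Before the data were examined, 29 gene lists were fixed: skeletal muscle, fatty acid oxidation and the citric acid cycle, basal keratinocytes, tongue epithelial differentiation, stress-activated keratinocytes, mitosis, DNA replication, matrix proteases, stromal matrix, factors of epithelial-mesenchymal transition (EMT), cytokines and chemokines, myeloid cells, lymphoid cells, interferon response, immune checkpoints, retinoid metabolism, NRF2 targets, p53 targets, oral carcinoma driver genes, EGF-family ligands and receptors with the related genes Met and Fgfbp1, Notch and Wnt, glycolysis and hypoxia, taste cells, salivary gland, adipocytes, endothelium, Schwann cells, red blood cells, and a sex check. For each list, the called members were counted, over all tested genes and adjusted over the list alone with the Benjamini-Hochberg method. A two-sided Fisher's exact test compared called members, in either direction, with the other tested genes, adjusted over the 29 lists with the Benjamini-Hochberg method. Genes are not independent replicates, so this test describes the list. The median log2 fold change of a list was placed among 10000 random lists of the same size, each member replaced by a tested gene of the same of 20 expression bins. That percentile describes these libraries and is not a test over animals.

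Named genes followed a rule fixed in advance. It took the 5 most raised and 5 most lowered called genes with at least 5 FPKM in the higher group, passing over predicted models, then the 2 most changed called members of each main list and the most changed of each secondary list at the same level, or the most abundant members where none passed. Called members moving against most of their list were added, as were Trp53, Cdkn2a, Notch1, Myc, Ccnd1 and Egfr, and 4 retinoid genes. A few genes that this rule or a list's count would name are not reported here. Other genes are named to fill out a list's count or to describe a run of neighbouring genes, and these were chosen after their values were seen.

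The steps were tested on simulated data. For the tumour against normal comparison, fold changes were drawn for 15686 genes from the deposited standard errors. With 50 planted genes per size, calls recovered 6% at a log2 change of 1, 58% at 2, 74% at 3 and 96% at 4. These calls used a Benjamini-Hochberg adjustment over the simulated genes, nearly all of them unchanged, and not the deposited q-values. The rates therefore need not hold for the deposited calls. Of 100 simulated lists with no shift, 4 fell outside the central 95% of random lists, and 99 of 100 lists shifted by a log2 change of 1 lay above it. These lists held genes drawn at random, with permuted fold changes. They check the procedure only, and do not show how often an unshifted list of co-expressed genes would fall outside. Alternatives were a q-value under 0.01, a Bonferroni limit over the tested rows, a minimum of 1 FPKM in the higher group, fold changes recomputed with a pseudocount of 1, and, for the lists, a background without muscle genes and re-centred fold changes. A Benjamini-Hochberg adjustment over this table alone was added after seeing the data. Alternatives planned for counts or for values per sample were not run, since the table has neither. The labels give no batch and no pairing. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.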

Results

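Gene expression was measured by poly(A) RNA sequencing in carcinogen-induced squamous cell carcinomas of the mouse tongue (4-NQO, 3 samples) and in normal, untreated tongues (5 samples), all from female C57BL/6 mice. The comparison asks which transcripts differ between the carcinoma and the normal organ. Normal tongue is a composite of stratified epithelium, skeletal muscle, glands, nerve and vessels. All expression values, fold changes and q-values below come from the authors' deposited table, which gives a single FPKM per group. The spread between samples therefore cannot be seen. The ± denotes the standard error of a log2 fold change implied by the authors' test, and how far it reflects that spread is not known. The deposited table lists Xist, the X-inactivation transcript, at 24.3 FPKM in normal tongue and 29.9 in tumours, and the 4 Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y at 0.00512 FPKM or less in both groups.

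Tumours had more of Sprr2, chemokine and matrix protease transcripts and less of hair-type keratin-associated transcripts. In the authors' deposited table, 988 of 15783 tested genes (6.26%) passed q under 0.05, 484 of them higher in tumours and 504 lower. Large changes were mostly increases: of the 580 called genes that differed at least 4-fold, 392 were higher and 188 lower, or 176 and 96 with a pseudocount of 1 FPKM. The most raised were 3 small proline-rich proteins of the cornified envelope. Sprr2d went from 0.266 to 896 FPKM (log2 fold change 11.72 ± 1.27, q listed as 0), Sprr2f from 0.1004 to 237 FPKM (11.21 ± 1.31, q listed as 0) and Sprr2e from 0.0084 to 133 FPKM (13.95 ± 3.76, q = 0.0114). The stromelysin Mmp10 followed, at 0.0152 FPKM in normal tongue and 10.4 in tumours (9.42 ± 1.57, q = 3.77e-07), with the kallikrein-related peptidase Klk6 (8.79 ± 2.38, q = 0.0118).

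The most lowered gene by the same rule was Ngp, a neutrophil granule protein made by precursors in bone marrow, at 9.79 FPKM in normal tongue and 0.0569 in tumours (−7.43 ± 1.10, q = 3.46e-09 in the authors' deposited table). The next were 4 keratin-associated proteins, structural proteins of hair that cross-link hard keratins: Krtap9-1 (−7.20 ± 1.17), Krtap4-2 (−6.98 ± 0.95), Krtap4-6 (−6.92 ± 0.94) and Krtap4-8 (−6.61 ± 0.92), with deposited q-values from 8.43e-11 to 1.56e-07. Sprr2 and Krtap genes are families of near-identical copies. The assignment of reads among copies by the authors is not known, so the value of any single member is uncertain. A single value per group also cannot show whether every normal tongue held the Krtap transcripts. A difference in the part of the tongue sampled was not tested. The precision of the deposited comparison set a floor on what could be called: the median standard error was 0.53 on the log2 scale and the smallest called change was 1.40, so a doubling was rarely detectable.

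**Figure D1:**
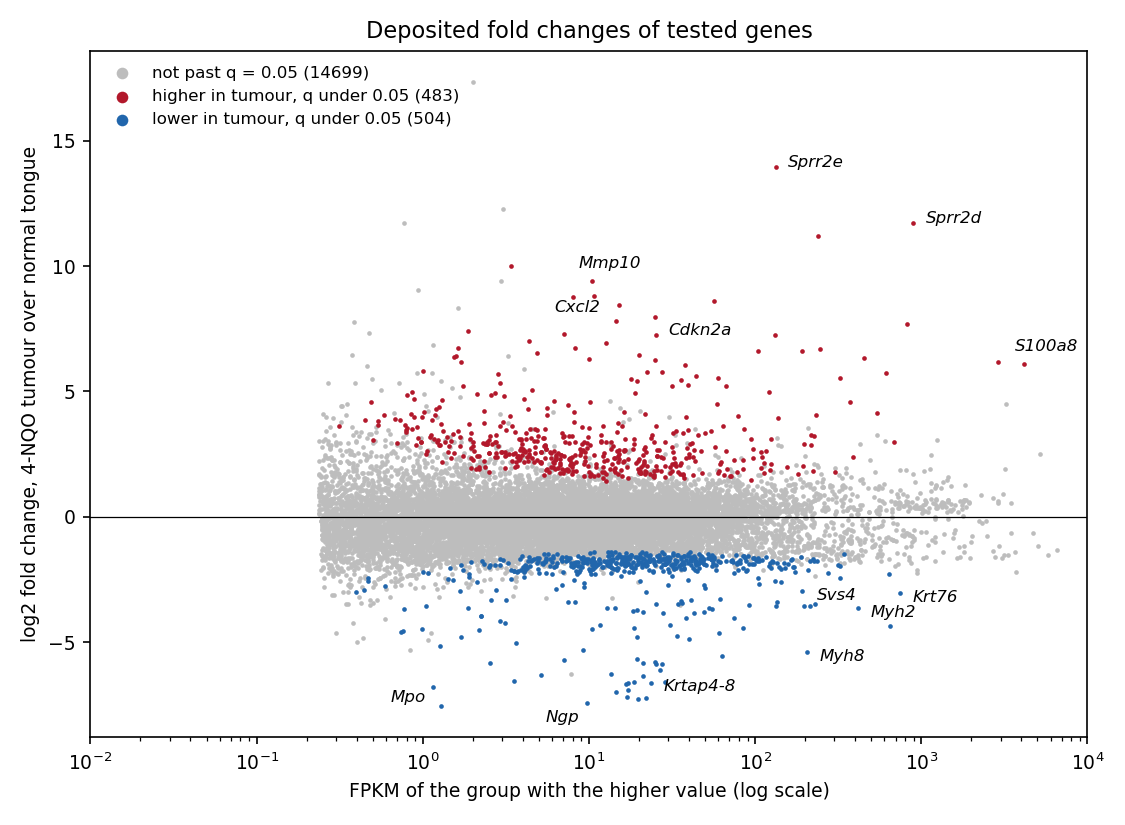
Each point is a tested gene in the authors' deposited table. The x axis is the FPKM of the group with the higher value (log scale) and the y axis the log2 fold change of tumour over normal tongue; red and blue points passed q under 0.05, and the 97 tested genes with a group listed at 0 are not drawn. Called genes lie at least 1.40 from 0, and rises reach 13.95 while falls end at −7.55.

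Among genes of stratified epithelium, several genes of basal cells and of activated keratinocytes were higher in the tumour tissue, while few differentiation genes were called. Of 13 tested basal keratinocyte genes in the authors' deposited table, 5 rose and none fell (Fisher's exact test of called members, adjusted p = 0.00465), and 8 passed when adjusted over the list alone, 6 of them higher. The list's median log2 fold change was 1.93, at percentile 100 of random lists. They included Lama3 and Lamb3, laminin chains of the basement membrane, the integrin chain Itga3 and P-cadherin, Cdh3. Cdh3 stood at 3.66 FPKM in normal tongue and 37.0 in tumours (3.34 ± 0.66, q = 4.62e-05). The basal keratin Krt5 was listed at 843 and 3201 FPKM with a standard error of 2.38 and did not pass (q = 1.00), and Krt15 (−1.53 ± 0.66, q = 0.350) and Dst (−1.49 ± 0.65, q = 0.365) had negative fold changes. The partner keratin Krt14 could not be compared, since its tumour value is listed at 0 with a failed estimate.

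Stress-activated keratinocyte genes showed 7 of 13 tested members higher and none lower in the authors' deposited table (adjusted p = 3.29e-05), 9 when adjusted over the list alone, with a median of 3.50 at percentile 100. Sprr2d and Sprr2h led (11.72 ± 1.27 and 6.71 ± 0.74). The calprotectin subunits S100a8 and S100a9, antimicrobial proteins of neutrophils and activated epithelium, went from 59.7 to 4134 FPKM (6.11 ± 0.88, q = 1.43e-09) and from 40.4 to 2900 FPKM (6.17 ± 0.92, q = 4.52e-09). The remaining called members were Sprr1b, Il1rn and Stfa1. Neutrophils also express S100a8, S100a9, Il1rn and Stfa1, and 7 genes of mature neutrophils had a median log2 fold change of 2.502 in the same table, all 7 positive. The wound keratin Krt17 was listed at 141 and 3227 FPKM but did not pass (4.51 ± 1.83, q = 0.274), and Krt6a, Krt6b, Krt16 and Krt75 each have a group listed at 0 by failed estimation.

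Among 14 tested genes of tongue epithelial differentiation, 1 rose and 2 fell, 3 also when adjusted over the list alone, and the median was −0.03 at percentile 45.4 of random lists (adjusted p = 0.118), turning to 0.02 when fold changes were re-centred and to 0.03 with a pseudocount of 1. Krt76, a keratin of oral suprabasal cells, fell from 746 to 89.7 FPKM in the deposited table (−3.06 ± 0.72, q = 0.00153), and Krt36, a hard keratin of filiform papillae, from 324 to 59.4 FPKM (−2.45 ± 0.64, q = 0.00821). Krt1, the suprabasal keratin of epidermis, rose from 2.42 to 38.2 FPKM (3.98 ± 0.55, q = 1.98e-10). Krt4 and Krt13, the major differentiation keratins of tongue, and Krt84 are listed at 0 in both groups by failed estimation, so the deposited table cannot show how they changed. Krt84 is listed at the same locus as Krt6a, Krt6b and Krt75, so its own level cannot be read from that failure.

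Cell division genes were higher. Of 24 tested mitosis genes in the authors' deposited table, 22 rose and none fell (adjusted p = 1.90e-23), 23 when adjusted over the list alone, with a median log2 fold change of 2.67 at percentile 100. Birc5, the survivin subunit of the chromosomal passenger complex, rose from 3.22 to 32.2 FPKM (3.32 ± 0.66, q = 5.96e-05), and the mitotic cyclin Ccnb1 rose 8.64-fold (3.11 ± 0.54, q = 1.67e-06). The other 2, Cdc20 and Kif20a, had log2 fold changes of 3.27 ± 1.49 and 2.84 ± 1.803. DNA replication genes were higher by less: 6 of 24 rose and none fell in the deposited table (adjusted p = 0.0145), 13 when adjusted over the list alone, and all 24 fold changes were positive with a median of 1.28 at percentile 100. Thymidine kinase Tk1 (2.38 ± 0.55, q = 0.0012) and the ribonucleotide reductase subunit Rrm2 (2.34 ± 0.54, q = 0.00117) were the most changed at 5 FPKM or more.

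The 18 tested driver genes of oral carcinoma showed 1 call in the authors' deposited table, and 1 when adjusted over the list alone (adjusted p = 1.00). Cdkn2a, which encodes the cell-cycle inhibitors p16Ink4a and p19Arf, rose 150-fold, from 0.167 to 25.2 FPKM (7.23 ± 1.37, q = 1.75e-05). The list's median was 0.39 at percentile 98.7. No call was made for Trp53 (0.82 ± 0.46, q = 0.714), Notch1 (0.28 ± 0.46, q = 1.00), Myc (1.14 ± 0.53, q = 0.468), Ccnd1 (0.31 ± 0.49, q = 1.00) or Egfr (0.61 ± 0.55, q = 1.00). Of 16 tested p53 target genes, 1 rose, 1 higher and 1 lower passed when adjusted over the list alone, and the median was 0.33 at percentile 94.7 (adjusted p = 1.00), or 0.21 with a pseudocount of 1. That gene was Pmaip1, the apoptosis activator Noxa, at 0.332 and 5.57 FPKM (4.07 ± 0.71, q = 1.51e-06), while the p53 target Cdkn1a was listed at 107 and 111 FPKM.

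Many protease genes of the extracellular matrix were higher in tumours, while few fibroblast matrix genes were called, 1 higher and 2 lower. In the authors' deposited table, 8 of 16 tested matrix protease genes rose and none fell (adjusted p = 1.82e-05), 11 when adjusted over the list alone, with a median of 2.34 at percentile 100. After Mmp10, the collagenase Mmp13 was the most changed, at 0.327 FPKM in normal tongue and 24.995 in tumours (6.26 ± 1.00, q = 7.57e-08). The others included Mmp3, Mmp9, Mmp12, Adam8 and the urokinase Plau. Among 20 tested stromal matrix genes 1 rose and 2 fell, 4 when adjusted over the list alone, and the median was −0.24 at percentile 13.01 (adjusted p = 0.229). Tenascin-C, Tnc, rose from 2.81 to 11.05 FPKM (1.97 ± 0.47, q = 0.00177). Fap, the fibroblast activation protein, fell from 5.19 to 1.43 FPKM (−1.86 ± 0.57, q = 0.0425), and lumican, Lum, from 56.4 to 17.3 (−1.70 ± 0.46, q = 0.0115). The EMT list had 1 call among 14 tested members, the transcription factor Snai2 (2.21 ± 0.50, q = 0.000975), 4 when adjusted over the list alone with 2 in each direction, and a median of −0.27 at percentile 19.1 (adjusted p = 0.823). In the deposited table Cdh1, the epithelial cadherin, was listed at 33.2 and 78.1 FPKM (q = 0.507) and Vim, the mesenchymal filament vimentin, at 247 and 131 (q = 0.906).

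Inflammatory signals were higher. Of 21 tested cytokine and chemokine genes in the authors' deposited table, 15 rose and none fell (adjusted p = 4.42e-13), 17 higher and 1 lower when adjusted over the list alone, with a median log2 fold change of 5.33 at percentile 100, or 2.18 with a pseudocount of 1 FPKM. The neutrophil-attracting chemokines Cxcl2 (0.0647 to 14.6 FPKM, 7.82 ± 1.12, q = 1.01e-09) and Cxcl3 (0.104 to 12.6 FPKM, 6.92 ± 1.09, q = 4.81e-08) were the most changed, and Cxcl1, Cxcl5, Csf3, Il1b, Il6, Tnf, Il23a and Ptgs2 were among the other calls. The member with a negative fold change was Cxcl12, at 36.5 and 14.2 FPKM (q = 0.384).

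Markers of the immune cells themselves were less uniform. Among 17 tested myeloid genes, 2 rose and 1 fell in the authors' deposited table, 6 when adjusted over the list alone, and the median was 0.28 at percentile 92.8 (adjusted p = 0.179). The risers were the activation receptors Trem1 and Clec4e, with log2 fold changes of 2.99 ± 0.91 (q = 0.0434) and 4.32 ± 1.20 (q = 0.0161). Mpo, the myeloperoxidase made by granulocyte precursors, fell from 1.29 to 0.00685 FPKM (−7.55 ± 1.86, q = 0.00333). The most abundant members did not pass: Arg1 was listed at 84.2 and 191 FPKM (q = 0.705), and Lyz2 at 129 and 76.7 (q = 0.824). Of 11 tested lymphoid genes 2 rose, 5 higher and 1 lower passed when adjusted over the list alone, and the median was 2.56 at percentile 100 (adjusted p = 0.253), or 0.41 with a pseudocount of 1. The T-cell receptor chain Cd3g went from 0.174 to 2.33 FPKM (3.74 ± 0.97, q = 0.00697) and granzyme B, Gzmb, from 0.0778 to 0.928 (3.58 ± 1.03, q = 0.0234). Its partner Cd3d missed the limit in the deposited table (3.10 ± 1.00, q = 0.0683), and the B-cell gene Cd79a had a negative fold change (−2.45 ± 1.11, q = 0.420).

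Interferon-response genes had 4 of 18 members higher in the authors' deposited table, 6 when adjusted over the list alone, and a median of 0.89 at percentile 100 (adjusted p = 0.0557). Oas1a, an antiviral oligoadenylate synthetase, rose 4.22-fold (2.08 ± 0.59, q = 0.0217), and the antigen-processing genes Psmb8 and Tap1 and the guanylate-binding protein Gbp2 were also called. The immune checkpoint list had 3 of 10 members higher, 6 when adjusted over the list alone, with a median of 2.00 at percentile 99.97 (adjusted p = 0.0555), or 0.77 with a pseudocount of 1. Those were Pdcd1, Icos and Cd80 at levels of 3.42 FPKM or less in tumours, whereas Cd274, the ligand PD-L1, was listed at 1.53 and 3.93 FPKM and did not pass (1.36 ± 0.55, q = 0.272).

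Genes of glutathione metabolism, growth-factor signalling and glucose uptake also had higher members. Among 18 tested NRF2 targets 5 rose and none fell in the authors' deposited table (adjusted p = 0.0170), 10 when adjusted over the list alone, with a median of 1.22 at percentile 100. The cystine importer Slc7a11 went from 1.26 to 21.7 FPKM (4.11 ± 0.61, q = 3.48e-09) and the glutathione transferase Gsta1 from 24.0 to 227 FPKM (3.24 ± 0.51, q = 5.64e-08). Gclc and Gclm, the subunits of the enzyme that limits glutathione synthesis, and Gsta2 were the other calls. Gsta1 and Gsta2 are close paralogs that may share reads. The list of EGF-family and related genes had 4 of 12 members higher (adjusted p = 0.0183), 5 higher and 1 lower when adjusted over the list alone, and a median of 0.90 at percentile 100. Amphiregulin, Areg, rose 43.5-fold in the deposited table, from 0.829 to 36.0 FPKM (5.44 ± 0.74, q = 6.14e-11), with the ligands Hbegf and Epgn and with Fgfbp1, a carrier of fibroblast growth factors. In the glycolysis and hypoxia list 5 of 20 members rose, 5 also when adjusted over the list alone, with a median of 0.59 at percentile 99.8 (adjusted p = 0.0216). Slc2a1, the glucose transporter GLUT1, went from 13.9 to 232 FPKM (4.06 ± 0.94, q = 0.00124), and Car9, Car12, Adm and Pfkl were called as well. Of 20 Notch and Wnt genes 1 rose, the Notch ligand Jag1 (1.81 ± 0.50, q = 0.0151), 3 in each direction passed when adjusted over the list alone, and the median was 0.28 at percentile 95.9 (adjusted p = 1.00).

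A few retinoid genes were higher. Of 19 tested members, the authors' deposited table called 3 higher and none lower (adjusted p = 0.217), 5 higher and 3 lower when adjusted over the list alone, and the median was −0.04 at percentile 47.7, above 0 when fold changes were re-centred. Aldh1a3, a retinaldehyde dehydrogenase that makes retinoic acid, went from 0.761 to 9.09 FPKM (3.58 ± 0.63, q = 1.86e-06). Lrat, which esterifies retinol for storage, rose from 0.289 to 3.16 FPKM (3.45 ± 0.70, q = 9.36e-05). The receptor gene Rarb was listed at 3.55 and 1.03 FPKM and missed the limit (−1.78 ± 0.58, q = 0.0769). Neither Aldh1a2 (−1.13 ± 0.66, q = 0.782), Crabp2 (1.29 ± 0.49, q = 0.207) nor Cyp26a1 (−1.05 ± 1.07, q = 1.00) passed.

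Genes of skeletal muscle and its oxidative metabolism had negative fold changes throughout, and few passed singly. All 22 tested skeletal muscle genes had negative fold changes in the authors' deposited table, with a median of −1.61 at percentile 0 of random lists, and 2 fell, or 5 when adjusted over the list alone (adjusted p = 0.851). The median standard error of these genes was 0.81 on the log2 scale, beside 0.53 over all tested genes with a finite fold. The fast myosin Myh2 fell from 414 to 33.0 FPKM (−3.65 ± 0.67, q = 7.74e-06) and the Z-disc protein Myot from 313 to 83.1 (−1.91 ± 0.54, q = 0.0195). A further 6 listed muscle genes, Acta1, Ckm, Myh1, Myh4, Atp2a1 and Tnnt3, have a normal value listed at 0 by failed estimation and tumour values between 386 and 2362 FPKM, so muscle transcripts were abundant in the tumour samples too. All 18 genes of fatty acid oxidation and the citric acid cycle had negative fold changes in a narrow range, from −1.98 to −1.13, with a median of −1.34 at percentile 0. Cpt1b, the muscle carnitine palmitoyltransferase, was the 1 call (−1.98 ± 0.57, q = 0.0241), and 13 passed when adjusted over the list alone (adjusted p = 1.00).

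Markers of other normal tongue tissues also had negative medians in the authors' deposited table, and these shifts accompany the epithelial and immune differences given above. The median was −1.41 for 11 Schwann cell genes, −1.39 for 10 adipocyte genes (−0.91 with a pseudocount of 1), −1.02 for 12 endothelial genes and −1.62 for 8 red blood cell genes, at percentiles of 0.03 or less, with every member negative. Calls were few, at most 1 per list, and included the endothelial cadherin Cdh5 (−1.47 ± 0.43, q = 0.0279) and the erythrocyte anion exchanger Slc4a1 (−4.78 ± 0.84, q = 2.36e-06), and no adipocyte gene passed. Fabp4, the most abundant of these, was listed at 264 and 177 FPKM (q = 1.00). When adjusted over the list alone, 9 Schwann cell, 7 endothelial, 3 adipocyte and 1 red blood cell gene passed as lower. Alpha-globin, in the entry that joins Hba-a1,Hba-a2, was listed at 566 and 201 FPKM (q = 0.670). Taste cell genes had no call among 8, or when adjusted over the list alone, with a median of −1.10 at percentile 2.37 (−0.28 with a pseudocount of 1, at percentile 4.25) and Entpd2 as the most abundant (−1.25 ± 0.47, q = 0.189). Of 14 salivary gland genes 3 fell and 1 rose, 4 also when adjusted over the list alone, with a median of −0.79 at percentile 1.09. The adjusted p of Fisher's exact test was 0.0267 for calls in either direction, so it does not test a lowering. Demilune cell proteins Dcpp1 (125 to 30.0 FPKM, −2.06 ± 0.47, q = 0.000883), Dcpp2 and Dcpp3 were lower. These 3 are members of a single family that may share reads, so they may not be separate changes. Lactoperoxidase, Lpo, was higher, from 0.072 to 2.12 FPKM (4.88 ± 0.86, q = 2.63e-06, or 1.54 with a pseudocount of 1). For the number called, the adjusted p was 0.777 for the Schwann cell list, 0.783 for the endothelial, 0.651 for the red blood cell and 1.00 for the adipocyte and taste cell lists.

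**Figure D2:**
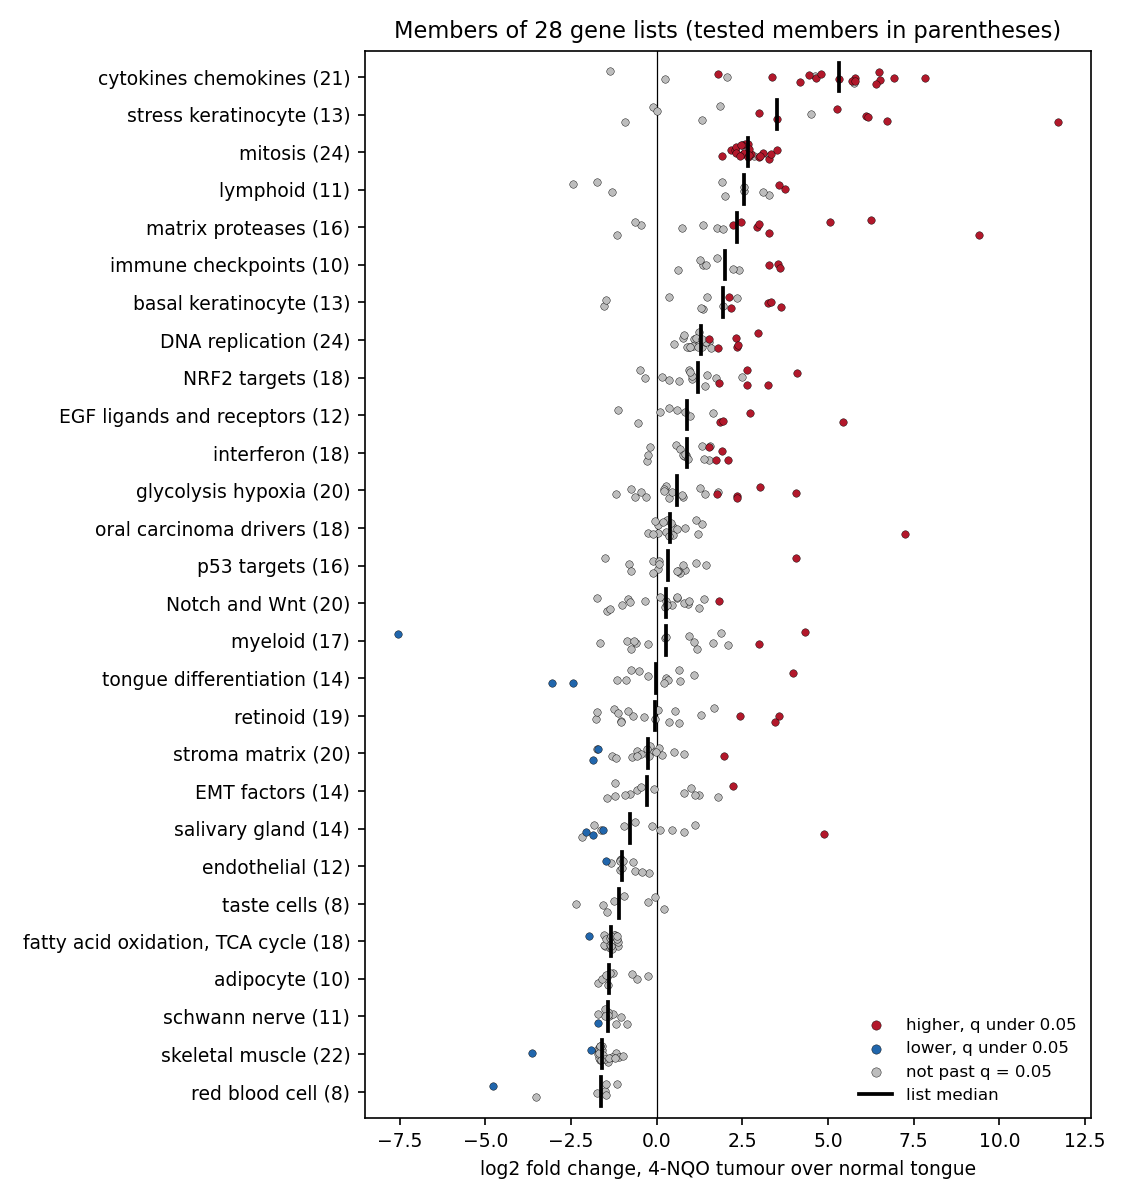
Each point is a tested member of 1 of 28 gene lists, placed by its log2 fold change of tumour over normal tongue in the authors' deposited table; vertical bars are list medians, red and blue points passed q under 0.05, and members with a group listed at 0 are not drawn. Medians run from 5.33 for cytokines and chemokines to −1.62 for red blood cell genes, and the members of the mitosis and oxidative metabolism lists sit close together.

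A pair of gene clusters held many of the most changed genes. In the authors' deposited table the Sprr cluster on chromosome 3 (92054569 to 92304415) holds 14 tested genes, 11 of them higher and none lower, with a median log2 fold change of 5.94. The 3 without a call, Sprr1a, Sprr3 and Sprr4, lie together at its end, where Sprr3 was listed at 903 and 624 FPKM. On chromosome 11 the keratin-associated protein cluster (99411446 to 99855308) holds 30 tested genes, predicted genes included, of which 29 fell and none rose, with a median of −6.19. Those 29 make up 15.4% of all genes called at least 4-fold lower. Neighbouring members are near-identical copies, so the number of separately changed genes may be smaller than the count.

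**Figure D3:**
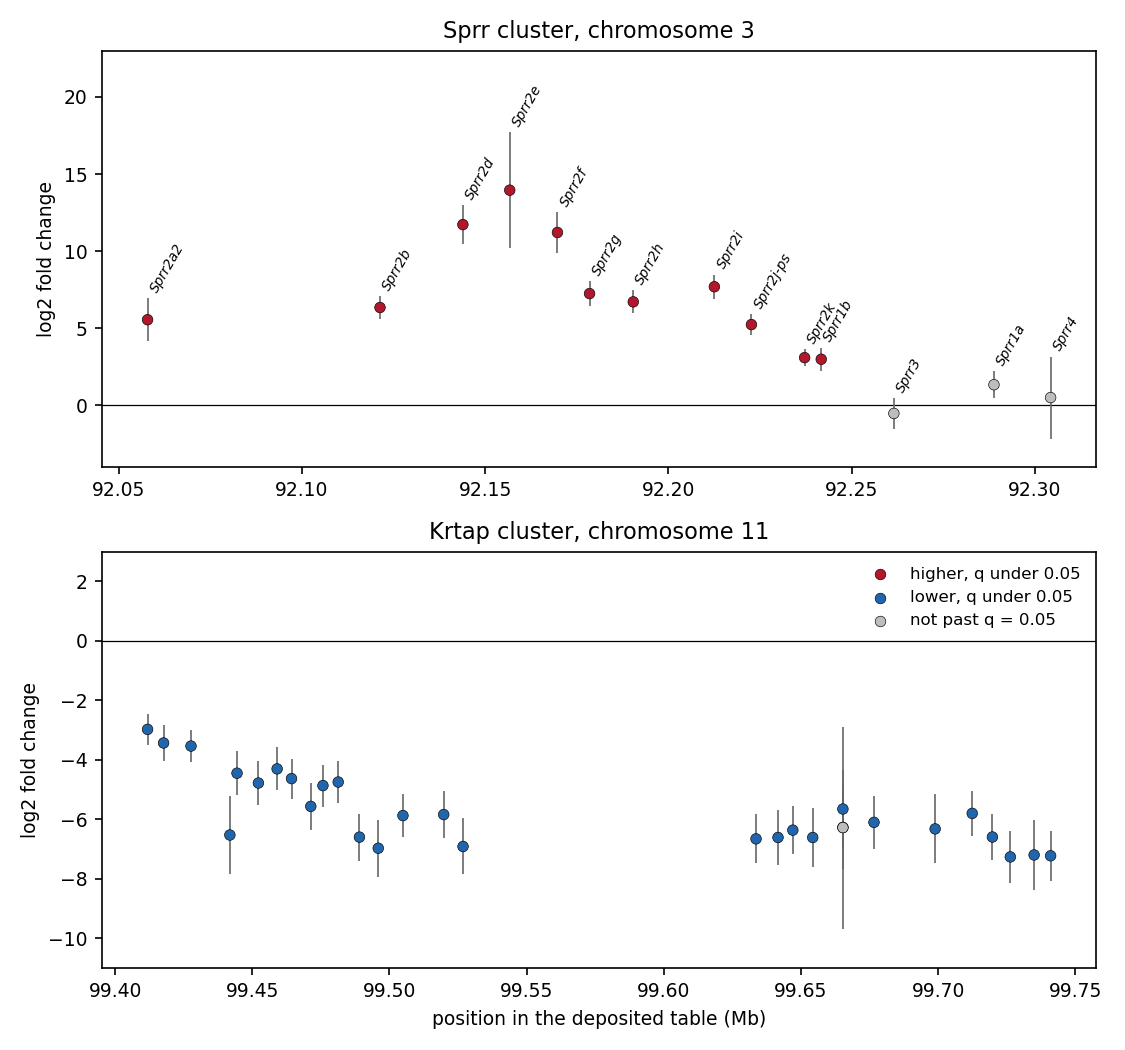
Log2 fold change of tumour over normal tongue (y axis, points with ± standard error from the authors' deposited statistic) against position in megabases in the table's own coordinates (x axis) for the Sprr cluster (upper panel) and the keratin-associated protein cluster (lower panel). In the upper panel 11 of 14 genes are called higher, and in the lower panel 29 genes are called lower, with 1 grey point that did not pass.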

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

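The Benjamini-Hochberg adjustment over this table was the test chosen after the data were seen. Under q below 0.01, 571 genes passed (310 higher, 261 lower). A Bonferroni limit over the tested genes left 198 (126 higher, 72 lower), the same numbers as among genes changed at least 4-fold. With fold changes recomputed after adding a pseudocount of 1 FPKM, 272 genes passed the 4-fold limit (176 higher, 96 lower). This count fell because the pseudocount shrinks the fold of weakly expressed genes. Adjusting over this table alone called 1420 genes (628 higher, 792 lower). A minimum of 1 FPKM in the higher group left 951 calls. No result changed direction past its threshold. Of 62 named genes, 9 were no longer called under q below 0.01 and 20 under Bonferroni, and Cd3d and Rarb were gained by the adjustment over this table. Of 28 lists, 21 lay outside the central 95% of random lists, 21 after re-centring by −0.04, 20 with the pseudocount, where taste cell genes had a median of −0.28, and 19 of 26 with the muscle and oxidative metabolism lists left out. Leave-one-out, other splits of the samples, count models, sample weights and camera or fry were not run, because the deposited table holds a single value per group. No paired analysis was possible because the labels pair no samples. Depth is unknown. The standard error limits what could be called, with a median of 0.88 under 1 FPKM, 0.46 between 10 and 100 FPKM and 0.58 above 100 FPKM.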

Other observations

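The gene families, the runs of neighbouring genes, the patterns weighed below, the salivary gland test and the medians with a pseudocount of the sets tested below, other than the skeletal muscle list, were chosen after the results were seen, while the predictions for the other tests were written before the tested values were seen. Further gene groups differed in the authors' deposited table. Among 248 families of genes sharing a name stem, each tested in both directions, 11 of 496 Fisher's exact tests had an adjusted p under 0.05. Besides the families described in the report, 12 of 31 keratins fell (adjusted p = 1.33e-08) and 3 rose (adjusted p = 0.917), the fallers including the hair keratins Krt31, Krt33a, Krt33b, Krt34, Krt35, Krt81, Krt83 and Krt86. Krt86 fell from 38.1 to 2.33 FPKM (log2 fold change −4.03). Of 16 Asb genes, substrate adaptors of ubiquitin ligases, 7 fell (adjusted p = 2.87e-05), with Asb15 at −2.20, and of 29 Klhl genes, also ligase adaptors, 6 fell (adjusted p = 0.0130). The median was −1.64 for the Asb and −0.49 for the Klhl genes, beside −1.61 for the skeletal muscle list, and muscle expresses members of both families. Of 33 kinesins, the microtubule motors, 10 rose (adjusted p = 4.08e-06), and the family median was 0.52. Those 10 include Kif11 and Kif23, which the mitosis list already counts. Of 12 Tmprss serine proteases 4 rose (adjusted p = 0.0160), with Tmprss11g at 1.27 and 15.7 FPKM. Calls were rare in either direction among 335 Zfp zinc finger genes, with 0 higher (adjusted p = 0.00415) and 2 lower (adjusted p = 0.0758).

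Called genes of the same direction lay next to each other more often than under permutation. With at least 4 called genes and gaps under 200 kb, the only setting tried, the deposited table held 10 runs with 93 called genes. Over 1000 permutations of the calls the median was 3 runs, the highest 10, and 1 permutation reached that number. A run on chromosome 16 (36120032 to 36455478) held the stefin A genes, inhibitors of cysteine proteases, with 9 of 10 tested genes higher and a median log2 fold change of 5.49. There Stfa3 went from 3.81 to 121 FPKM and Csta from 17.5 to 84.1. On chromosome 5 (91188325 to 91577458) 7 of 10 genes were higher, the chemokines Cxcl1, Cxcl2, Cxcl3, Cxcl5 and Ppbp and the EGF-family ligands Epgn and Areg. Many members of these runs are close copies that can share reads.

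Genes of bone marrow and bone were lower in the tumour value of the deposited table: Ngp (−7.43), Camp (−5.70), Mpo (−7.55) and the bone sialoprotein Ibsp (−6.79). Fewer mature neutrophils in the tumours is argued against, since 7 mature neutrophil genes had a median log2 fold change of 2.502 (0.82 with a pseudocount of 1), all of them positive and 2 called. Bone marrow or bone taken with some of the normal tongues may account for it: 14 other marrow and bone genes, of which Alas2 is also in the red blood cell list, had a median of −2.81, 13 of them negative and 1 called. Most of the 14 lie near 0 FPKM, and with a pseudocount of 1 their median of −0.44 was nearer to 0 than the −1.59 of skeletal muscle, so this support is weak and rests on a few more abundant genes such as the osteocalcin gene Bglap2, listed at 25.2 and 2.26 FPKM. Which tongues carried this signal cannot be seen without values per sample.

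The myosin genes Myh3, Myh6, Myh8 and Myh13, of developing, cardiac or specialised muscle, were lower in the deposited table by more than other muscle genes, with log2 fold changes of −5.32, −5.84, −5.40 and −5.88. A lower share of muscle in the tumours is argued against as the whole cause, since the skeletal muscle list had a median of −1.61, although Myh6, the least abundant, was at −1.76 with a pseudocount of 1. Fewer developing or regenerating muscle cells may contribute, and 9 genes of such cells had a median of −2.02. With a pseudocount of 1 their median was −1.21, less negative than the −1.59 of skeletal muscle. The −2.02 met the bound of −1.5 written beforehand, but the muscle list meets it as well. The test therefore does not decide, a condition added after its value was seen. A difference in the part of the tongue sampled was not tested.

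Seminal vesicle genes were present in both group values, and higher in normal tongue, although the labels give females only. Svs4 was listed at 198 and 16.8 FPKM (−3.56 ± 0.90, q = 0.00468) and Svs5 at 228 and 20.2. Of 8 such genes 7 were called lower in tumours, and all 8 lay between −3.85 and −3.22 with a median of −3.49. A lower share of minor salivary gland is argued against as the whole cause, for the gland genes listed. The salivary gland list had a median of −0.79, mixing 9 negative and 5 positive members, and its lowest was −2.19. None fell as far as the seminal vesicle genes, but the bounds of this test were set after the results were seen. RNA or reads of male accessory glands may be the source, with more in the normal than in the tumour libraries. The tumour value holds Svs4 and Svs5 as well, so a source in normal libraries alone would not account for both values. Another 10 genes of these glands had a median of −2.53 (−1.14 with a pseudocount of 1), 8 of them negative and 2 called. Those 2 were Spinkl (21.0 and 1.52 FPKM) and Sva (19.5 and 1.48). Against a full set, Tgm4 had a log2 fold change of 0.20, and Y-linked genes were near 0 in both groups. The library or step at which such RNA entered cannot be seen.

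A further pattern, with a pair of tests whose predictions were written beforehand, was also tested, and was set aside once the seminal vesicle genes were found, so 8 tests were run in all and 6 are weighed above. The RNAs Rmrp (1.95 and 192 FPKM) and Rpph1 (1.06 and 104 FPKM) had a log2 fold change of 6.62 each in the deposited table. Another 90 RNAs without a poly(A) tail had a median of 1.09 (1.06 with a pseudocount of 1), 78 of them positive and 12 negative. None of the 90 was called, and their median standard error was 29.8. The 17 tested genes of the RNA polymerase III machinery had a median of 0.08.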
